A study of Akkermansia muciniphila with 6 samples.

How the data were processed

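RNA-seq of total RNA was carried out on 6 culture samples of *A. muciniphila* EB-AMDK39, with 1 library per hour of culture. RNA was extracted with an RNeasy kit and libraries were made with a TruSeq kit for stranded total RNA that depletes ribosomal RNA, per the labels' protocols. Trimmomatic, a read trimmer, STAR, an aligner, and HTSeq, a read counter, are named without versions in the submitters' processing notes. The genome build, the annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads shared between near-identical or overlapping genes could therefore have been split or dropped.

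The authors deposited a table of raw read counts for 2630 locus tags, with 1 column per hour and no total or unassigned entry. They also deposited a table of CPM for 2568 of these tags. Each CPM value equalled the deposited count divided by 1 size per library, with a relative deviation of at most 5.6e-09. That size was between 1.209 and 1.432 times the total of the deposited counts, so the CPM columns summed to between 698000 and 827000, and how it was set is not given in the sources used here. Of the 62 tags left out of the CPM table, all but 1 had at most 34 counts in any library. The first tag of the count table had from 1396 to 7708 counts and was left out as well.

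Groups and hours came from the labels: before mid-log (6, 7 and 8 h) and after mid-log (10, 11 and 12 h). Replicate numbers only name the samples in order and pair nothing, so no block was fitted. The depth was 7860925 to 12863996 counts per library. Exact Clopper-Pearson intervals at 95% were used for shares of single libraries, and 3 counts were taken as the floor.

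The main test was the quasi-likelihood test of edgeR 4.0.16 (glmQLFit with legacy = FALSE, and glmQLFTest) in R 4.3.3 on the deposited counts, with TMM normalization. Low tags were removed with filterByExpr (minimum count 10, minimum total 15), which left 2574 tags; the 56 not tested held 0.0036% of the counts. Tags with a Benjamini-Hochberg adjusted p under 0.05 were called. Fits held the group alone, the group with hour as a number, hour alone, hour with its square, and the interaction of hour and group. Standard errors were taken as the size of the log2 fold change over the square root of the F statistic. Levels in CPM are TMM-normalized, and the floor in CPM is over the total count of the library. Principal components used log2 CPM with a prior count of 2.

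The named tags were to be those with the largest rises and falls among tags with an adjusted p under 0.05, a mean of at least 20 CPM and no overlap between the groups; 665 passed. Because the tags could not be paired with names, 2 that rose and 2 that fell were taken. For the same reason the 38 gene lists fixed before the data were examined, covering functions such as translation, the cell envelope, secretion and stress, could not be matched to any tag. The tests of those lists were not run, and structural RNA could not be left out.

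Neighbouring tags were compared in the order of their numbers, with tags counted as 1 place apart when their numbers differed by 5, the step of the numbering. Fold changes or calls were shuffled among tags 10000 times, and a running median over 101 tags was subtracted in one test. The change between successive libraries was computed both with all tags of at least 20 CPM and without the 100 most abundant tags.

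The scripts were tested on simulated counts for the 2574 tested tags, in 5 simulations with 200 changed tags each. Counts were drawn independently for each tag, and unchanged tags held no trend over the hours. Tags of the real libraries moved together over the hours, so the rates below need not hold for them. The group test recovered 70.6% of 2-fold and 98.0% of 4-fold changes with a mean of 8.6 false calls. The group term beside hour recovered 2.2% and 38.2% with 1.4 false calls. For changes given per 2 hours, the hour term recovered 70.2% and 99.6% with 10.4 false calls, and the interaction 41.8% and 94.6% with 10.8 false calls.

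Alternatives set before the data were examined were 3 other scalings (DESeq2 size factors, upper quartile, total counts), no filter and a filter of 50 counts in 3 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), the older dispersion route of edgeR, each library left out, hours 8 and 10 left out, hour in place of the group, and 2 fold-size thresholds. A limma trend fit on log2(CPM + 1) of the authors' CPM was run too, with pseudocounts 0.5 and 5 and with a minimum mean of 10 CPM. Fold changes on that scale understate those of low tags. The authors' size per library was between 1.311 and 1.342 times the total after TMM, so their CPM nearly share the scaling of the main fit. The alternatives for the interaction were chosen after seeing the data.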

Results

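RNA-seq was carried out on the wild-type *Akkermansia muciniphila* strain EB-AMDK39, a mucin-degrading anaerobe of the gut that the study places in its clade AmII. The cells grew in soy-peptone medium at 37 °C without oxygen, and 1 library was made at each of 6 hours of culture. The 3 libraries of 6, 7 and 8 h belonged to the group before mid-log phase, when the strain had no inhibitory effect on clade AmI. The 3 libraries of 10, 11 and 12 h belonged to the group after mid-log phase, when it had that effect, which the study ascribes to extracellular vesicles shed by AmII. The comparison asks which transcripts differed between these states. Genes were listed by locus tag, a numbered identifier given to each annotated gene. The numbers were taken to follow the order along the assembly, which could not be checked without coordinates. The sources used here do not pair the tags with gene names or products.

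The deposited counts came to 12863996 reads at 6 h, 8345593 at 7 h, 8690148 at 8 h, 7940656 at 10 h, 7860925 at 11 h and 8424768 at 12 h. Of 2630 locus tags, between 2621 and 2627 had at least 1 count in each library. The 10 most abundant tags of a library took from 16.83% of its counts at 8 h (95% exact binomial interval 16.81 to 16.86%) to 18.44% at 12 h (18.42 to 18.47%). A floor of 3 counts corresponded to between 0.233 and 0.382 CPM (counts scaled to the total of the library), and intervals and floors cover counting error only. The labels do not say whether the libraries came from separate cultures, so p-values measure only the spread between these samples. That spread includes any change over the 3 hours within a group.

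The transcriptome moved in 1 main direction with the hour of culture. The first principal component held 87% of the variance of log2 CPM. Its scores were -23.16 at both 6 and 7 h, -13.98 at 8 h, -0.51 at 10 h, 24.77 at 11 h and 36.04 at 12 h, so the groups did not overlap. The second component held 8.45%, and the 10 h library had its highest score, 13.87. Over the 2204 tags with a mean of at least 20 CPM, the root mean square log2 change was 0.103 from 6 to 7 h, against 0.0655 from counting noise. It was 0.293 from 7 to 8 h, 0.359 over the 2 hours from 8 to 10 h, 0.583 from 10 to 11 h and 0.319 from 11 to 12 h. The 10 h library was thus nearer to the 8 h library (r = 0.986 across tags) than to the 11 h library of its own group (r = 0.967), tags not being independent replicates. The closest pair, 6 and 7 h (r = 0.998 across tags), still differed beyond counting noise, with a chi-square of 4.46 per degree of freedom. Counting noise leaves out the spread between library preparations, so this does not show that the 2 libraries are independent. They were counted as 2 samples.

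**Figure D1:**
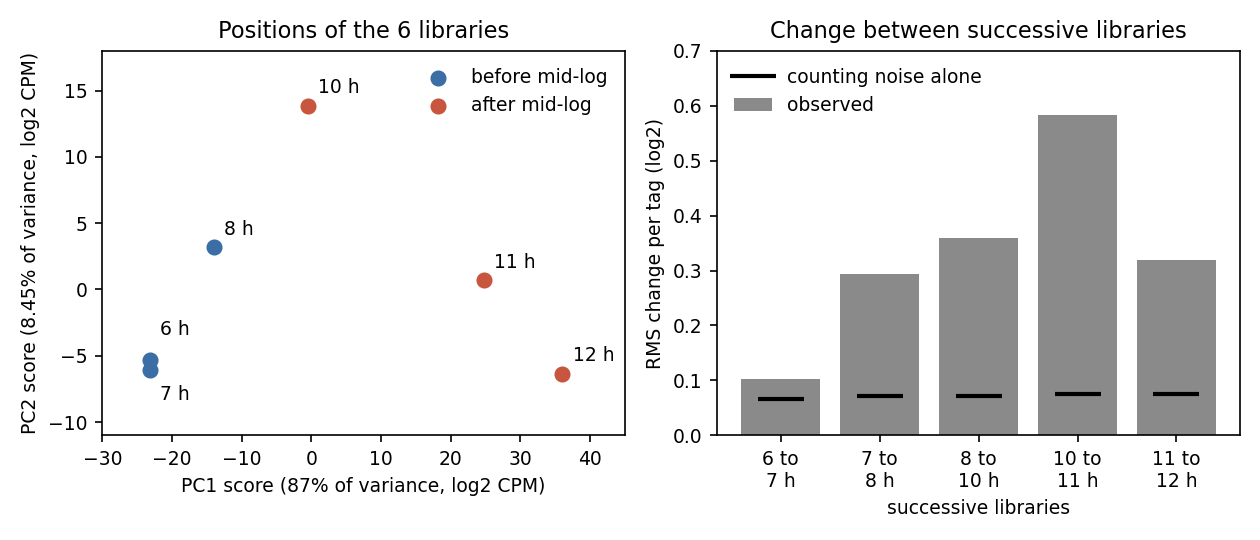
Left, scores of the 6 libraries on the first and second principal components of log2 CPM, with blue points before and red points after mid-log; right, root mean square log2 change per tag between successive libraries (bars) and the part that counting noise alone would give (black lines). The groups do not overlap on the first component, and the tallest bar, 0.583, is the step from 10 to 11 h.

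After mid-log phase, 506 tags were higher and 270 were lower than before it, 776 of the 2574 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Rises were larger than falls, with a median log2 fold change of 1.22 among tags called higher and -0.78 among tags called lower. A change of 2-fold or more was seen in 349 of the risen and 74 of the fallen tags, and one of 4-fold or more in 58 and 16. With scaling by total counts alone, 271 risen and 143 fallen tags reached 2-fold, and the median log2 fold changes of called tags were 1.17 and -0.78. Tags called higher took 11.8% ± 2.18 (SD, n = 3) of the counts before mid-log and 29.9% ± 8.65 after, and tags called lower went from 10.8% ± 1.53 to 4.76% ± 1.26. These tags were chosen on the same libraries, so the shares describe their weight and are not separate evidence. In 1481 tags (57.5%) the 3 values of one group lay entirely above or below those of the other, where libraries in random order would give 10%. A steady change with hour parts the groups in the same way, so this share does not single out a difference at mid-log. The number of calls changed with each library left out. It fell to 6 without the 6 h library, 2 without 7 h, 310 without 8 h, 7 without 11 h and 236 without 12 h, and rose to 1843 without 10 h, with 910 higher and 933 lower. Fits with a library left out set 2 libraries against 3 and have less power, so a lost call does not show that a difference vanished. DESeq2 called 1203 tags, and scaling by total counts alone turned the balance to 418 higher and 546 lower.

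**Figure D2:**
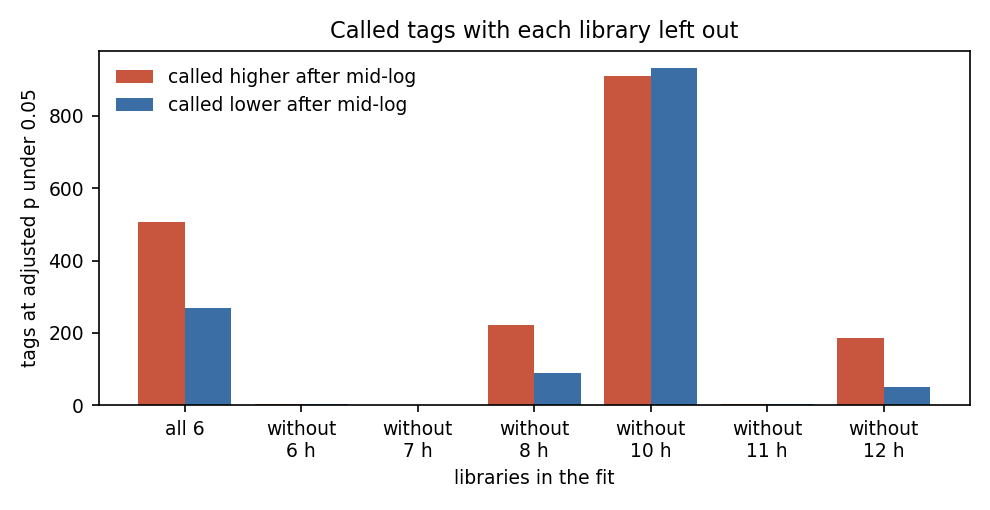
Number of tags called higher (red) and lower (blue) after mid-log at an adjusted p under 0.05, with all 6 libraries and with each library left out in turn. Leaving out 6, 7 or 11 h leaves at most 7 calls in all, and leaving out 10 h gives 1843.

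The tags with the largest rise and fall among those of at least 20 CPM were taken by a rule set before the data were examined. DMI75_RS06740 rose 11-fold, from 87.8 ± 26.5 to 963 ± 783 CPM (SD, n = 3 per group), a log2 fold change of 3.46 with a standard error of 0.70 (edgeR adjusted p = 0.022). Its level was 118 CPM at 8 h, 239 at 10 h, 856 at 11 h and 1794 at 12 h. Without the 12 h library its log2 fold change was 2.64 (edgeR adjusted p = 0.0449). DMI75_RS00205 rose 8.16-fold, from 2173 ± 1164 to 17730 ± 9783 CPM, a log2 fold change of 3.03 ± 0.60 (SE; edgeR adjusted p = 0.0209). It stood at 1456 CPM at 7 h and 26720 CPM at 12 h.

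The 2 tags with the largest fall have neighbouring numbers. DMI75_RS06520 had a log2 fold change of -3.76 ± 0.43 (SE; edgeR adjusted p = 0.00852), a 13.5-fold drop from 951 ± 394 to 70.2 ± 25.3 CPM (SD, n = 3 per group). DMI75_RS06515 had one of -3.65 ± 0.42 (SE; edgeR adjusted p = 0.00852), a 12.5-fold drop from 90.8 ± 35.7 to 7.23 ± 2.86 CPM. Both were highest at 7 h, at 1224 and 117 CPM, and had already dropped to 499 and 50.01 CPM at 8 h, before the boundary between the groups. All 4 named tags kept their direction with any library left out. Without hours 8 and 10 their log2 fold changes were larger in size, at 4.23 for DMI75_RS06740, 3.97 for DMI75_RS00205, -4.37 for DMI75_RS06520 and -4.28 for DMI75_RS06515. Without 6, 7 or 11 h all 4 lost their calls, with edgeR adjusted p from 0.0633 to 0.11. Their log2 fold changes moved little in these fits, at 3.35 to 3.53 for DMI75_RS06740 and 2.83 to 2.97 for DMI75_RS00205. They were -3.60 to -3.52 for DMI75_RS06520 and -3.52 to -3.41 for DMI75_RS06515. Without 8 h DMI75_RS06740 lost its call (edgeR adjusted p = 0.0551).

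**Figure D3:**
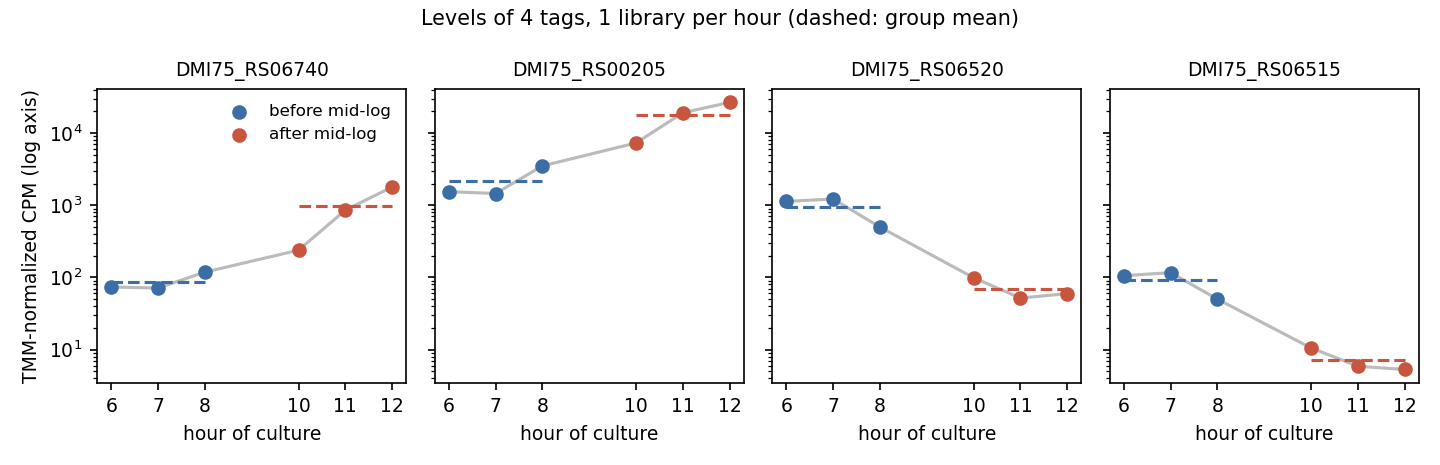
TMM-normalized CPM (log axis) of the 4 named tags against hour of culture, with 1 point per library, blue before and red after mid-log, and dashed lines at the group means. DMI75_RS06740 and DMI75_RS00205 climb from 7 h to 12 h, while DMI75_RS06520 and DMI75_RS06515 drop between 7 and 11 h.

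The 2 most abundant tags did not pass the test. The most abundant tag over all libraries took 5.49% ± 0.16 of the counts before and 5.55% ± 0.73 after mid-log (SD, n = 3; log2 fold change 0.17, edgeR adjusted p = 0.725). The next took 4.50% ± 0.23 and 3.68% ± 0.49 (log2 fold change -0.14, edgeR adjusted p = 0.757).

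Changed tags lay beside one another in the tag numbering, which was read as gene order without coordinates. The log2 fold changes of tags 1 place apart correlated at 0.506 across tags, and those 2, 3 and 5 places apart at 0.251, 0.177 and 0.102. Each was above the highest value of 10000 shuffled orders (one-sided permutation p = 1e-04, the smallest they can give, adjusted p = 0.00018 over 7 distances). At 10 places the correlation was 0.0333 (permutation p = 0.05, adjusted p = 0.07), and at 20 places it was -0.00686 (permutation p = 0.6, adjusted p = 0.6). Of the 776 called tags, 319 (41.1%) stood in runs of 3 or more called the same way, where shuffled orders held 56 at the median and 105 at most. There were 21 runs of 5 or more tags called higher, against at most 5 in shuffled orders, and 2 such runs called lower, against 0 at the median and 2 at most (one-sided permutation p = 7e-04, adjusted p = 0.00088 over 5 statistics of runs). The longest run called lower held 6 tags, against 3 at the median and 7 at most (permutation p = 0.002, adjusted p = 0.002).

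These runs differed widely in level. DMI75_RS06520 and DMI75_RS06515 belonged to a run of 6 fallen tags with log2 fold changes from -3.76 to -1.19, whose median level went from 380 to 77.4 CPM. The other run of 6 fallen tags ranged from -3.56 to -0.62 and went from 71.0 to 18.1 CPM. Among the risen runs, one of 6 tags went from a median of 418 to 2150 CPM, with log2 fold changes from 2.33 to 2.97. The longest, of 23 tags, had log2 fold changes from 0.70 to 1.5 and went from 22.2 to 48.2 CPM. A run of 19 tags went from 4.24 to 12.7 CPM. DMI75_RS00205 stood in a run of 3 risen tags, and DMI75_RS06740 had no neighbour called higher.

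**Figure D4:**
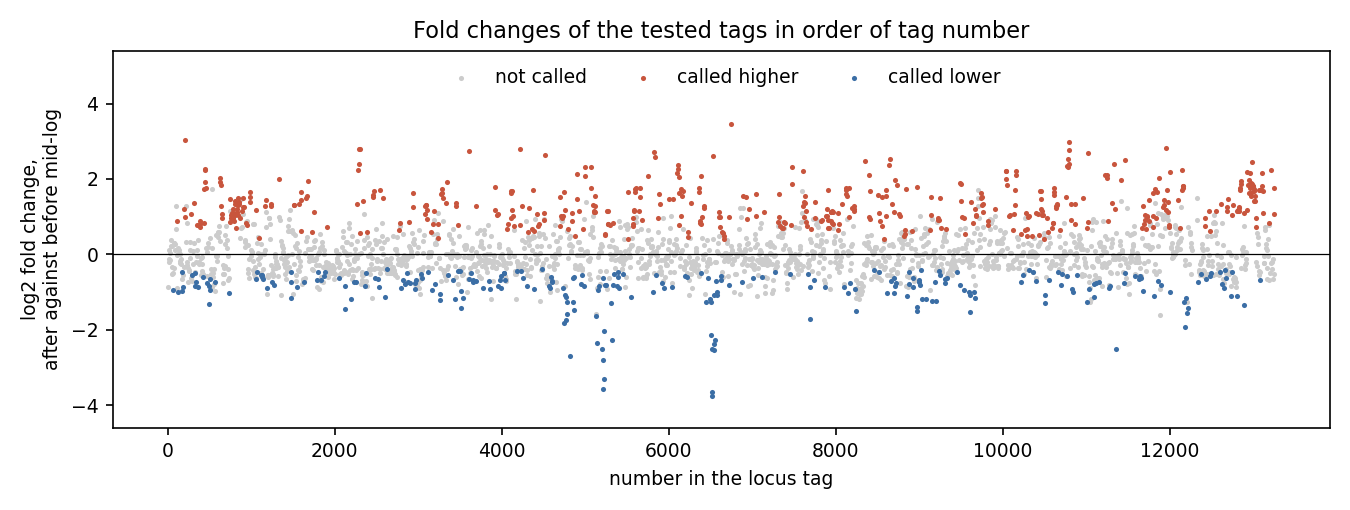
Log2 fold change, after against before mid-log, of each tested tag in order of the number in its locus tag; red and blue points were called higher and lower at an adjusted p under 0.05, grey points were not called. Called tags gather in columns of points, such as the fallen tags around DMI75_RS06520 with log2 fold changes down to -3.76.

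A second question was whether the groups differed by more than a steady change per hour. With hour in the edgeR fit beside the group, 0 tags were called for the group, 26 had an unadjusted p under 0.05 and the smallest adjusted p was 0.753. DESeq2 called 6 tags in this fit and limma-voom 0. For the change per hour shared by both groups, edgeR called 0 tags, 573 had an unadjusted p under 0.05 and the smallest adjusted p was 0.22. DESeq2 called 82 tags for it and limma-voom 0. On simulated counts the group term of this fit recovered 2.2% of 2-fold and 38.2% of 4-fold changes. Most steps of these sizes were thus missed there, and could have been missed in the real libraries. Beyond the shared slope, the log2 difference between the groups was -1.87 for DMI75_RS06520 (edgeR unadjusted p = 0.0403) and -0.33 for DMI75_RS06740 (edgeR unadjusted p = 0.785). Neither passed the test (edgeR adjusted p = 1 for both). This fit assumes 1 slope for both groups. The slope of DMI75_RS06740 differed between them (edgeR interaction of hour and group, adjusted p = 0.0263), so its -0.33 does not describe a step.

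With hour alone in the edgeR fit, 803 tags rose and 753 fell. These 1556 calls held 773 of the 776 tags called between the groups, in the same direction, and a further 783. Levels rose at each of the 5 steps from 6 to 12 h in 176 tags and fell at each in 254, where random orders would give 3.6 of each. The highest level was reached at 12 h in 888 tags (34.5%) and at 6 h in 504. It was reached at 7 h in 406, at 8 h in 182, at 10 h in 304 and at 11 h in 290.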

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

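The tests of depth, of a swap of libraries and every test of the slope difference itself were chosen after the results were seen; the test without the most abundant tags was not. The change per hour differed between the groups for 389 tags (edgeR interaction of hour and group, 952 at an unadjusted p under 0.05, smallest adjusted p 0.0245), which is why this result is singled out. In 164 tags the slope was steeper upward after mid-log, with a median of 0.00658 log2 units per hour before and 0.664 after. In 225 tags it was steeper downward, with medians of 0.00873 and -0.607. Of the 389 tags, 106 were also called between the group means, where 776 of all 2574 tested tags were. These were 83 of the 164 steeper upward and 23 of the 225 steeper downward. For DMI75_RS06740 the slope was higher by 1.11 log2 units per hour after mid-log (edgeR adjusted p = 0.0263). The count fell to 0 without the 6, 8 or 10 h library and rose to 826 without 11 h, in fits with 1 residual degree of freedom. It was 305 without 7 h and 566 without 12 h.

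The 10 h library lay nearer to 8 h than to 11 h, and the largest change between successive libraries came at 10 to 11 h. Sequencing depth is argued against, since the totals of the 10 and 11 h libraries differed 1.01-fold and those of 8 and 10 h 1.09-fold, while the largest difference in totals, 1.54-fold between 6 and 7 h, came with the smallest change. A few abundant tags are also argued against, since the change was 0.577 without the 100 most abundant, against 0.341. A swap of a library between the groups would put them out of order on the first principal component, where a gap of 13.5 parted the highest library before from the lowest after mid-log. The large step stood alone, since the change from 11 to 12 h was 0.319, near the 0.293 from 7 to 8 h before mid-log. Culture density at sampling was not used here, so a culture that lagged at 10 h and a biological change at that hour both stay open and untested.

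The 10 h library also had the highest score on the second principal component, and levels that peak or dip between the first and last hours could give such a score. In a fit with hour and its square, the squared hour was called for 0 tags in edgeR, with 786 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0702. The absence of calls had been set to rule this explanation out, and with that many small unadjusted p-values it does not. Those p-values do not favour a peak or dip either. The squared hour also picks up levels that move the same way throughout but faster at later hours. Root mean square slopes were 0.143 log2 units per hour before and 0.406 after mid-log, over the 2204 tags with at least 20 CPM. The test therefore cannot decide, and the explanation stays open.

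The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split called 776 tags and the highest of the others 0, so that 1 split reached the real count. It is also the only split that keeps the hours in order, as each of the others mixes early and late libraries. A steady change with hour would favour the real split in the same way, so this contrast does not single out mid-log. For the group term beside hour, all 10 splits called 0 tags, the real one included.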

How the results depend on the processing

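Tests of the slope difference were chosen after seeing the data. The 776 group calls became 1203 with DESeq2 (500 lower), 1808 without hours 8 and 10 (926 higher, 882 lower) and 1556 with hour in place of the group (803 higher, 753 lower). They became 423 at 2-fold or more (74 lower), 64 in a test against 1.5-fold (46 higher, 18 lower), and with total counts 546 were lower. The 2 thresholds select fewer tags by construction. Hour in place of the group tests another term, and leaving out hours 8 and 10 drops the 2 libraries nearest the boundary between the groups. Beyond that, the cause was not tested for settings other than the thresholds. With 1 library left out the count ranged from 2 to 1843, higher calls from 0 to 910, lower calls from 2 to 933, and slope differences from 0 to 826. All 776 tags were also called by DESeq2 and without 10 h, and 667 by limma-voom. Other scalings but total counts, both filters, limma-voom, the older edgeR route and the authors' CPM gave 619 to 773 calls. The authors' CPM nearly share the scaling of the main fit, so they are no separate check of it. The 0 calls for the group beside hour and for the hour became 6 and 82 with DESeq2, and stayed at 0 in the other settings run.

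The 4 named tags kept their direction in all 19 settings, and lost calls only when 1 library was left out. Log2 fold changes ranged from 2.64 to 4.23 for DMI75_RS06740, 2.61 to 3.97 for DMI75_RS00205, -4.37 to -3.52 for DMI75_RS06520 and -4.28 to -2.74 for DMI75_RS06515. Leaving out hours 8 and 10 gave the largest size for each, leaving out 12 h the 2.64, and the authors' CPM with pseudocount 5 the -2.74. No paired analysis was possible because the replicate numbers follow the order of the samples only. Leaving out structural RNA and the tests of gene lists were not run, since the tags could not be paired with names. Depth limits tags near the floor of 0.233 to 0.382 CPM.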

Other observations

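The tests of scaling at 2-fold or more and from the median, of the trend at 5 places and of background in tags of at least 10 CPM were chosen after the results were seen. Slopes per hour were larger after than before mid-log in most tags. Over the 2204 tags with at least 20 CPM, the root mean square slope was 0.143 log2 units per hour before and 0.406 after, and 1788 tags had the larger slope after against 416 before. No test was made of this pair of values, and the slopes after mid-log include the large step from 10 to 11 h. Of the tags with a slope called different, 80 of the 164 steeper upward and 123 of the 225 steeper downward had slopes of opposite sign in the 2 groups. The median slopes before mid-log were only 0.00658 and 0.00873 log2 units per hour in these sets. With medians that small, about as many tags have either sign before mid-log, so these counts do not show a reversal of trend.

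Changed tags gathered next to one another in the numbering. Reads counted for overlapping neighbours would tie tags next to each other only. Yet the correlation of log2 fold changes 3 places apart was 0.177, above the highest shuffled value of 0.0858. That argues against overlap as the only source. How much of the correlation of 0.506 at 1 place came from shared reads cannot be told, since the treatment of such reads is not given. A smooth trend along the numbering would be removed by a running median, yet 94.1% of the correlation at 1 place was left, 82.0% at 2 places and 71.0% at 3. At 5 places 44.0% was left, a drop of 0.057. The drop at 20 places, with no correlation to remove, was 0.0629, so the running median cannot tell a trend apart there. Yet a trend broad enough for it to remove would also tie tags 20 and 50 places apart. Correlations there were -0.00686 and 0.00145, which argues against such a trend as the main source of the 0.102 at 5 places. Transcription of neighbouring genes as operons is a candidate explanation and remains a hypothesis, since positions and strands were not used here and no biological explanation was tested.

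Of the called tags 65.2% rose. The balance of all calls depends on the libraries and the model, with 49.4% rises without the 10 h library, 51.2% without hours 8 and 10, and 51.6% with hour in place of the group. It depends on the scaling too: 43.4% rose with total counts alone, which moved the median log2 fold change by -0.156 against TMM and so favours falls. Changes of 2-fold or more did not turn with the scaling, as rises made up at least 65.5% of such called tags under each of the 4 scalings. Rises also made up at least 59.4% of called tags 1.5-fold or more from the median (416 rises and 284 falls with total counts). Subtracting the median takes out most of the shift made by the scaling. The second measure could therefore hardly turn and says little about scaling. Higher power for abundant tags is argued against, since rises were above 50% in 4 of 4 bins of abundance. For the larger rises, a rise in even background is argued against too. The median rise was 108 CPM among the 462 risen tags of at least 10 CPM, against 1.27 CPM at the 5th percentile. That median is set by abundant tags and does not cover those nearer 10 CPM. The share of rises was highest, 79.2%, in the least abundant bin (median 17.2 CPM). For the 203 tags under 10 CPM, of which 44 rose and 7 fell, such a background may contribute, as the 5th percentile was 1.25 times higher after mid-log; it cannot be told apart from expression there, a value between the bounds set for either reading.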
